A study of Rattus norvegicus with 32 samples.

How the data were processed

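The series holds RNA sequencing of the hippocampus of 32 rat pups, 1 hippocampus per pup, from dams on an iron-sufficient or an iron-deficient diet and treated with intranasal insulin or not. Whether the pups of a group came from 1 litter or several is not stated, so the p-values measure the spread between these pups. The labels give the age at collection as either of 2 postnatal days without saying which applies to a sample. Insulin began after the earlier of these days, so the insulin-treated pups were collected on the later one. For the control groups the day is not settled by the labels. If it was the earlier one, comparisons of insulin with control would also be comparisons of age. The values below argue against this, since myelin genes rise strongly between the 2 days. Of 25 myelin and oligodendrocyte genes 0 differed between IS insulin and IS control (median log2 fold change 0.08). In all 19 genes differed there, 1 of them by at least 2-fold. Between ID insulin and ID control 3 of the 25 were higher and 1 lower (median 0.16). The sample titles hold a first number that coincides with the group, except that ID control has 2 of them, and a second number within it.

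The deposited table gives counts of reads per gene. Per the submitters' processing notes, the authors trimmed reads with Trimmomatic (version 0.40), inspected them with FastQC, aligned them with HISAT2 (version 2.1.0) and counted them with featureCounts, and edgeR is named among the tools. The notes list a rat and a mouse genome build without saying what each was for. All gene identifiers in the table are rat identifiers. Whether counting used the strand, and how reads that fit several places were treated, is not stated, so genes that overlap, antisense genes and near-identical copies are uncertain. No coordinates are given, because the available annotation is of another assembly. Gene symbols were taken from the deposited table, in which 25 names had been turned into dates by a spreadsheet. These and unnamed genes were tested but not named.

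The table held 32883 genes, of which 9663 had no count in any library, and no columns of other samples. Total counts were 19619345 to 28062630 per library. The smallest difference between any 2 libraries of a group was a chi-square of 5.77 per gene, so no library was a copy of another of its group.

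Counts were analysed in R (version 4.3.3) with edgeR (version 4.0.16): TMM normalization, filterByExpr by group, which kept 15439 genes, and the quasi-likelihood F-test (glmQLFit and glmQLFTest, two-sided) with 1 coefficient per group over all 32 libraries, which left 28 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and a gene with an adjusted p under 0.05 was called. The comparisons were ID control with IS control, ID insulin with ID control, IS insulin with IS control, ID insulin with IS control, ID insulin with IS insulin, and the interaction of diet and insulin. Libraries of title numbers 70 and 69 were compared in a fit of the 9 ID control libraries alone. CPM values use TMM-scaled library totals.

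For gene lists, camera in limma (version 3.58.1) was run on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 29 lists within a comparison. Camera with an estimated correlation and fry stood beside it. Members called were counted after adjustment over all genes and after adjustment over the list alone. The lists cover iron handling, hypoxia, glycolysis, nuclear and mitochondrial respiratory chain genes, cholesterol synthesis, insulin, IGF and mTOR signalling, immediate early genes, synapses, brain cell types, neighbouring tissues, stress, glucocorticoid, interferon and ribosomal protein genes, and a list of Y-linked genes served only as a check. Igf2, Rheb and Cspg4 each stood on a pair of lists.

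The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. By that rule, in each of the first 3 comparisons the 8 genes with the largest increase and the 8 with the largest decrease were named among those called, with a mean log2 CPM of at least 1 and a gene symbol. Added to these were up to 3 called genes per list with the lowest adjusted p, and 7 single genes whatever their result: Tfrc, Bdnf, Insr, Igf1r, Mbp, Camk2a and Slc2a1. In the other comparisons, genes already named and up to 4 per direction were named. Of the genes this rule gave, 2 are not reported here.

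The alternatives fixed in advance were DESeq2 (version 1.42.0, independent filtering off), DESeq2 size factors in edgeR, no count filter, a filter of 1 CPM in 7 libraries, the compared groups alone, limma voom with sample quality weights, the second title number as a block, the mean of the Y-linked list as a covariate, ID control libraries of title number 69 or 70 alone, and each library left out in turn. Alternatives chosen after the data were seen were the earlier quasi-likelihood method of edgeR, removal of ID insulin replicates 3 and 5 together, the means of the choroid plexus, blood, meninges and thalamus lists as covariates, 2 further lists (core clock, and motile cilia and ependyma), and the counts of genes moved back with ID control divided into parts. Each count of genes or lists was also obtained for 100 divisions of the same libraries into groups of the same sizes, the real one included.

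The fits were tested on simulated counts with the means and totals of these libraries, in which 50 genes at each of 4 fold sizes were changed. Genes varied independently of each other in them. Shared differences in tissue content or title number and an outlying library were not simulated. Recovery may therefore be lower, and false calls more frequent, in the real libraries. For ID insulin with ID control, 70% of genes changed 1.25-fold, 72% of 1.5-fold, 92% of 2-fold and 98% of 4-fold were recovered by edgeR, and 8 of the unchanged genes among 15341 were called. For IS insulin with IS control the shares were 52%, 82%, 86% and 100%, and 5 unchanged genes were called. For ID insulin with ID control, DESeq2 recovered 70%, 74%, 92% and 98% with 12 unchanged genes called, and limma voom 70%, 70%, 86% and 98% with 6.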

Results

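Gene expression was measured by RNA sequencing in 1 hippocampus from each of 32 rat pups, which fell into 4 groups by maternal diet and treatment. The diet was either iron sufficient (IS) or iron deficient (ID) through gestation and the first postnatal week. Pups received intranasal insulin in the weeks that followed or served as controls. There were 8 libraries in IS control, 9 in ID control, 7 in IS insulin and 8 in ID insulin. Total counts per library ranged from 19619345 to 28062630. Their means were 23598700 ± 2920350 in IS control, 22496000 ± 2031000 in ID control, 23330700 ± 2381390 in IS insulin and 23714500 ± 2420850 in ID insulin (SD, n = 8, 9, 7 and 8). Of 32883 genes in the table, 15439 had enough counts to be tested. The series asks how insulin given through the nose alters hippocampal gene expression after perinatal iron deficiency.

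Several properties of the libraries varied within groups and enter the comparisons below. Ttr, the transthyretin transcript of the choroid plexus, ranged from 8.38 to 3024 CPM (counts scaled to library size) in IS control, 1074 to 5102 CPM in ID control, 17.8 to 4010 CPM in IS insulin and 277 to 5561 CPM in ID insulin. Mitochondrially encoded transcripts took between 6.84% and 11.99% of the counts of a library. The Y-linked transcripts Eif2s3y and Kdm5d summed to more than 10 CPM in 4 of 8 IS control, 3 of 9 ID control, 3 of 7 IS insulin and 4 of 8 ID insulin libraries. The other libraries had at most 0.529 CPM. ID insulin replicate 3 stood apart as a whole: it differed from the 7 others of its group by a chi-square of 46.1 to 102 per gene, while no other pair of libraries within a group exceeded 36.4. The sample titles carry a first number whose meaning is not given. It was 71 for all IS control, 72 for all IS insulin and 73 for all ID insulin libraries, and 69 for 5 and 70 for 4 of the ID control libraries. A difference between groups therefore could not be separated from a difference between these numbers, except inside ID control.

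Iron deficiency without insulin was examined by comparing ID control with IS control. Tfrc (ENSRNOG00000001766), the transferrin receptor through which cells take up iron, was higher in ID control, at 169 ± 19.7 CPM against 117 ± 6.55 CPM (SD, n = 9 and 8). All 9 ID control libraries lay above every IS control library (log2 fold change 0.53, SE 0.07, adjusted p = 1.16e-04). The zinc transporter gene Slc39a12 (ENSRNOG00000025639) was lower, at 2.93 ± 0.675 CPM against 20.4 ± 10.5 CPM (log2 fold change -2.81, SE 0.45, adjusted p = 0.00212), with 6 of 9 libraries below all IS control libraries. Single IS control libraries ranged from 2.97 to 38.4 CPM, so a level as low as in ID control also occurred without iron deficiency. The scavenger receptor gene Scara3 fell from 73.9 ± 8.31 to 52.6 ± 4.70 CPM (log2 fold change -0.49, adjusted p = 0.00128). Vav2, which encodes a guanine nucleotide exchange factor, fell from 30.3 ± 4.95 to 17.5 ± 1.12 CPM (log2 fold change -0.78, adjusted p = 2.26e-04). Both were below every IS control library in 9 of 9 ID control libraries. In all, 45 genes differed, 27 higher and 18 lower in ID control.

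The genes named by the size of their change are called genes with an established symbol and a mean log2 CPM of at least 1, and genes outside these limits can have larger changes. Within them, decreases were also seen in the actin-capping gene Capg (log2 fold change -1.09), the calcium channel subunit gene Orai2 (-0.58), Rab36 (-0.33), Gramd2b (-0.29) and Entpd5 (-0.29). Increases were seen in Plac9 (1.43), the protease inhibitor genes Serpinb1a (1.12) and Spint1 (0.75), the complement component C7 (1.11), Clec3b (0.67), the matrix proteoglycan gene Prelp (0.57) and the tight junction gene Ocln (0.52). Of the genes singled out in advance besides Tfrc, none passed the test. The adjusted p was 0.615 for Mbp, 0.677 for Camk2a, 0.894 for Igf1r, 0.986 for Insr, 0.957 for the glucose transporter gene Slc2a1 and 0.840 for Bdnf.

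Of 29 gene lists fixed before the data were examined, 11 were called as sets with the preset correlation and 0 with an estimated correlation. Of 17 endothelium and pericyte genes, 1 was higher (Ocln), 0 lower and 16 not called, and 8 were higher when adjusted over the list alone. Their median log2 fold change was 0.21 (adjusted p = 6.91e-10, and adjusted p = 0.331 with an estimated correlation). Of 22 genes for iron uptake, storage and export, 1 was higher (Tfrc), 0 lower and 21 not called. Adjusted over the list alone 1 was higher and 1 lower (median 0.06, adjusted p = 0.0425, and adjusted p = 0.331 with an estimated correlation). The choroid plexus list had a median of 1.19 with 0 of 15 genes called (adjusted p = 4.75e-11, and adjusted p = 0.361 with an estimated correlation). Its level in single libraries spanned -3.89 to 1.25 in IS control against -0.21 to 1.97 in ID control on the log2 scale. Of 11 meninges and fibroblast genes 0 were called over all genes and 5 were higher when adjusted over the list alone (median 0.26, adjusted p = 2.96e-04). Of 22 interferon response genes 0 were called and 4 were higher over the list alone (median 0.18, adjusted p = 0.00462). Both lists had adjusted p = 0.361 with an estimated correlation. The lists for nuclear oxidative phosphorylation (median 0.06) and cytosolic ribosomal proteins (0.05) were called higher. Those for myelin and oligodendrocyte (-0.13), oligodendrocyte precursor (-0.08), glutamatergic synapse (-0.05) and glucocorticoid-responsive genes (-0.09) were called lower. Each of these 6 lists had 0 members called over all genes, and adjusted p = 0.361 to 0.752 with an estimated correlation. The 18 other lists, among them the immediate early gene, hypoxia-inducible, glycolysis and immature neuron lists, gave adjusted p = 0.0705 to 0.944.

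The count of 45 was 114 with DESeq2, 242 with limma voom and 10 with the means of the choroid plexus, blood, meninges and thalamus lists as covariates, and 23 to 28 when any of ID control replicates 7 and 9 and IS control replicates 1, 4 and 8 was left out. Of the 16 called genes named here, Tfrc, Vav2 and Scara3 were called in every setting. With the 4 ID control libraries of number 70 alone 9 were not called: Slc39a12, Prelp, Clec3b, Spint1, Capg, Gramd2b, Serpinb1a, Ocln and Entpd5. With those of number 69 alone 7 were not called: Rab36, Prelp, Clec3b, Plac9, Gramd2b, Serpinb1a and Entpd5. Of 32 fits with 1 library left out the call was lost in 24 for Clec3b, 23 for Prelp, 17 for Gramd2b, 9 for Entpd5, 4 for Serpinb1a and 3 for Plac9.

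**Figure D1:**
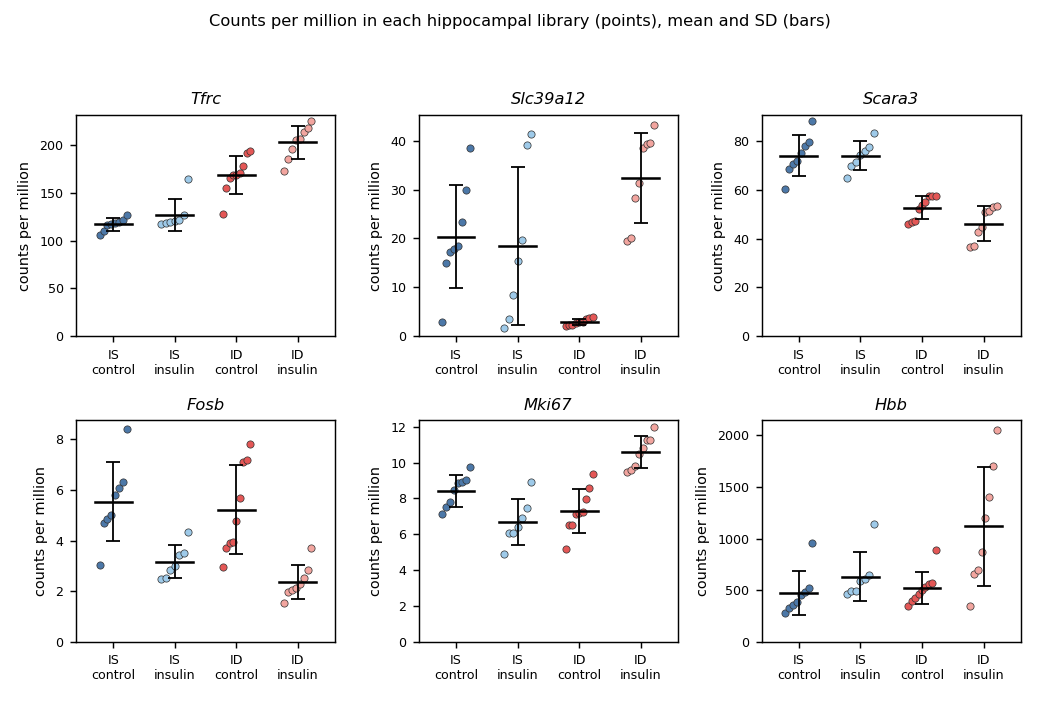
CPM (y axis, linear, starting at 0) of 6 genes in the 4 groups (x axis), with each library as a point and the group mean and SD as bars. Tfrc is higher in both ID groups (169 ± 19.7 and 203 ± 17.4 CPM) than in IS control (117 ± 6.55 CPM), and Slc39a12 is low in ID control (2.93 ± 0.675 CPM) and at 32.5 ± 9.20 CPM in ID insulin.

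Insulin in iron-deficient pups was examined by comparing ID insulin with ID control. Immediate early genes, whose transcription follows neuronal activity, were lower with insulin. Fosb fell from 5.23 ± 1.78 to 2.38 ± 0.670 CPM (log2 fold change -1.15, SE 0.20, adjusted p = 0.00241). Fos fell from 13.4 ± 2.88 to 7.72 ± 1.45 CPM (-0.79, adjusted p = 0.00434) and Egr2 from 6.15 ± 2.04 to 2.99 ± 0.979 CPM (-1.03, adjusted p = 0.00889; SD, n = 9 and 8). Genes of dividing cells and young neurons were higher. Mki67, a marker of proliferating cells, rose from 7.30 ± 1.23 to 10.6 ± 0.910 CPM with all 8 ID insulin libraries above every ID control library (0.54, adjusted p = 0.00254). The kinetochore gene Cenpf (0.49) and doublecortin, Dcx (0.27), rose as well. Slc39a12, low in ID control, rose to 32.5 ± 9.20 CPM in ID insulin (log2 fold change 3.47, SE 0.44, adjusted p = 2.56e-05, 8 of 8 libraries above all of ID control). Tfrc, already raised in ID control, rose further from 169 ± 19.7 to 203 ± 17.4 CPM (0.26, adjusted p = 0.0243), and so did Ncoa4, the receptor for breakdown of ferritin (0.20, adjusted p = 0.00618). The other 20 of 22 genes for iron uptake, storage and export were not called, and neither was that list (median 0.01, adjusted p = 0.255, and adjusted p = 0.439 with an estimated correlation). In all, 589 genes differed, 302 higher and 287 lower, and 101 of them by at least 2-fold.

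Of 26 immediate early genes 0 were higher, 5 lower and 21 not called, and 15 were lower when adjusted over the list alone. Their median log2 fold change was -0.29, and the list was called with the preset correlation (adjusted p = 6.67e-12) and with an estimated one (adjusted p = 0.0300). Of 20 immature neuron and proliferation genes 3 were higher, 0 lower and 17 not called. Over the list alone 5 were higher, and the median was 0.26 (adjusted p = 2.22e-04, and adjusted p = 0.0300 with an estimated correlation). These were the 2 of 17 called lists that held with an estimated correlation. Without ID insulin replicates 3 and 5 the median of the immediate early genes was -0.23 with 3 lower, and that of the immature neuron list was 0.19 with 2 higher.

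Among genes of other cell types and neighbouring tissue, 6 of 11 meninges and fibroblast genes were lower and 5 not called, including the retinoic acid synthesis gene Aldh1a2 (-0.80), collagen Col1a1 (-0.61) and biglycan, Bgn (-0.43). When adjusted over the list alone 8 were lower (median -0.51, adjusted p = 3.23e-07, and adjusted p = 0.161 with an estimated correlation). Vtn (-0.48), Cdh5 (-0.37) and Itm2a (-0.28) were the 3 of 17 endothelium and pericyte genes that were lower, and 0 were higher. Those called lower over the list alone were 7 (median -0.20, adjusted p = 5.00e-06, and adjusted p = 0.298 with an estimated correlation). Of 9 blood genes 4 were higher and 5 not called. The globin gene Hbb was at 1117 ± 580 against 521 ± 159 CPM (1.10), and the erythroid heme synthesis gene Alas2 (1.15) and the red cell anion exchanger gene Slc4a1 (1.3) were higher as well. Over the list alone 5 were higher (median 0.75, adjusted p = 1.23e-04, and adjusted p = 0.350 with an estimated correlation). Of 12 thalamus and habenula genes 2 were higher, Prkcd (1.28) and Patj (0.71), and 1 lower, Lhx9 (-0.71). With adjustment over the list alone 6 were higher and 1 lower (median 0.53, adjusted p = 0.0110, and adjusted p = 0.439 with an estimated correlation). Prkcd reached 172 CPM in ID insulin replicate 5 and lay between 10.6 and 43.6 CPM in the 7 other libraries of that group, and it was not called without that library or without any 1 of ID control replicates 3 to 9. The striatal list was not called and 1 of its 11 genes, Isl1, was higher (2.85). Isl1 reached 5.23 CPM in ID insulin replicate 8 and at most 1.78 CPM in the others, and its call was lost in 10 of 11 settings and in 23 of 32 fits with 1 library left out.

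In the oligodendrocyte lineage, 2 of 11 precursor genes were higher, Gpr17 (0.28) and Vcan (0.22), and 3 over the list alone (median 0.12, adjusted p = 0.00155, and adjusted p = 0.161 with an estimated correlation). Of 25 myelin and oligodendrocyte genes 3 were higher, including Enpp6 (0.44) and Gjc3 (0.44), and 1 lower, Mal (-0.48). Over the list alone 7 were higher and 1 lower (median 0.16, adjusted p = 1.62e-05, and adjusted p = 0.439 with an estimated correlation). Of 24 cholesterol synthesis genes 3 rose, including Hsd17b7 (0.27) and Sc5d (0.13), and 0 fell. Adjusted over the list alone, 4 were higher and 1 lower (median 0.07, adjusted p = 0.00420, and adjusted p = 0.439 with an estimated correlation). Of 17 glucocorticoid-responsive genes 1 was higher and 3 lower, Nfkbia (-0.50, not called without ID control replicate 3), Per1 (-0.41) and Errfi1 (-0.34). Over the list alone 1 was higher and 8 were lower (median -0.26, adjusted p = 1.23e-04, and adjusted p = 0.161 with an estimated correlation). Of 22 interferon response genes 1 was higher, Rsad2 (1.25), and 2 lower, Ifi27 (-1.0) and Ifit3 (-1.04). The microglial genes Cd74 (-1.02) and Tmem119 (-0.28), the pyramidal cell genes Coch (-0.93) and Wfs1 (-0.38), and the synaptic gene Nrgn (-0.32) were lower. So were the glycolytic gene Aldoa (-0.19), the respiratory chain genes Ndufb10 (-0.27), Cox4i1 (-0.21) and Ndufa10 (-0.16) and the ribosomal protein gene Rpl14 (-0.25). Their lists and that for interferon were called lower, with medians of -0.12 to -0.02, and gave adjusted p = 0.407 to 0.684 with an estimated correlation.

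The insulin, IGF and mTOR signalling list was not called, although 2 of its 34 genes were lower, the translation repressor gene Eif4ebp1 (-0.53) and Igfbp4 (-0.33). Insr, Igf1r, Bdnf, Camk2a, Mbp and Slc2a1 did not pass the test, with adjusted p = 0.0589 for Slc2a1 and 0.171 to 0.900 for the others. The hypoxia-inducible genes Ndrg1 (-0.37) and Mxi1 (-0.16), the astrocyte gene Gjb6 (-0.48) and the heat shock gene Hspa4l (0.18) were called within lists that were not. The 12 lists not called, which also included the mitochondrially encoded, GABAergic, neocortex, ER stress, dentate granule cell and choroid plexus lists, gave adjusted p = 0.0562 to 0.842. Outside the lists and within the same limits on symbol and level, the largest decreases were in H3f3c (-2.21), the brain serine protease gene Prss12 (-1.67, adjusted p = 5.69e-06), gamma-synuclein, Sncg (-1.51), Clip3 (-1.46), Tnnt2 (-1.16), the prostaglandin D synthase gene Ptgds (-1.15) and Plac9 (-1.13). Among the largest increases were those in the vesicular monoamine transporter gene Slc18a2 (2.19), Pnpla1 (1.36) and Baiap3 (1.28). ID insulin replicate 8 was the highest of its group in Baiap3 (129.7 CPM, against 7.59 to 33.3 CPM in the others) and in Slc18a2 (18.3 CPM, against 1.10 to 9.04 CPM), and Baiap3 was not called without it or without any 1 of 9 other libraries. Reads of H3f3c may be shared with near-identical histone genes, and those of the globin genes with each other, so their values are uncertain.

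The count of 589 was 819 with DESeq2, 150 with the 5 ID control libraries of number 69 alone, 232 with the 4 of number 70 alone, 278 with the 2 compared groups alone and 358 without ID insulin replicates 3 and 5. It was 323 without ID control replicate 5 and 31 with the tissue list means as covariates. Of 63 called genes that the naming rule gave, only Prss12 and Slc39a12 were called in all 13 settings and without each single library. Among the others, Hbb, Slc4a1, Tfrc, Cenpf, Patj, Prkcd, Baiap3, Isl1, Pnpla1, H3f3c, Clip3, Tnnt2, Ptgds, Vcan, Gjc3, Sc5d, Per1, Nfkbia, Nrgn, Wfs1, Cdh5, Igfbp4, Ifit3, Lhx9, Hspa4l, Aldoa and Ndufa10 were not called without ID insulin replicates 3 and 5. Other settings cost more calls, so a gene missing from this list is not thereby secure. With the direction kept, 57 were lost with the tissue list means as covariates, 40 with number 69 alone and 36 with number 70 alone. Fos was lost with number 69 alone and with the covariates, and Egr2 with the covariates. Calls also depended on single libraries. Of 32 fits with 1 library left out, Hspa4l lost its call in 15 and Cdh5 in 13. Lhx9 and Cox4i1 lost theirs in 7 each, and these are not the only such genes.

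**Figure D2:**
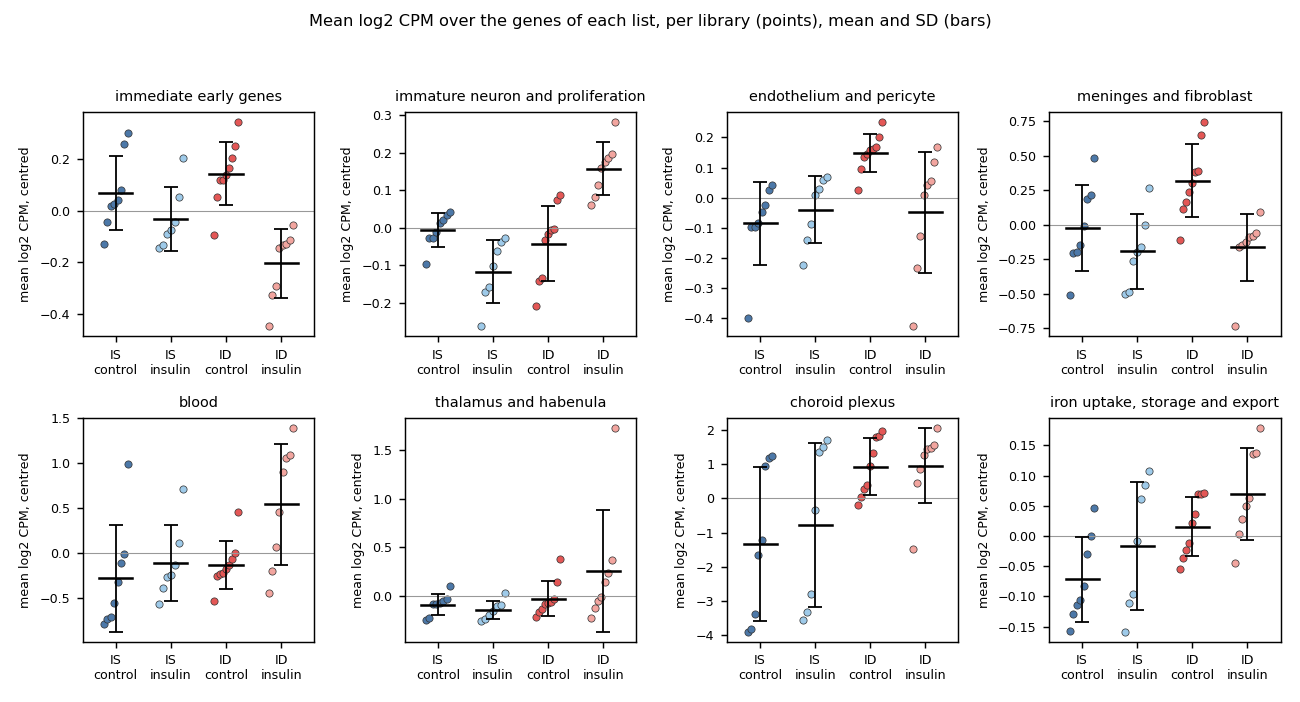
Mean log2 CPM over the genes of 8 lists, centred on the mean of all libraries (y axis), in the 4 groups (x axis), with each library as a point and the group mean and SD as bars. Immediate early genes lie at -0.20 ± 0.14 in ID insulin against 0.15 ± 0.12 in ID control, and 1 ID insulin library stands apart in the thalamus and habenula list at 1.73.

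Insulin in iron-sufficient pups was examined by comparing IS insulin with IS control. Dpysl3, a cytoskeletal gene of growing neurites, fell from 72.4 ± 6.95 to 55.7 ± 7.20 CPM (log2 fold change -0.38, SE 0.07, adjusted p = 0.0282), with all 7 IS insulin libraries below every IS control library (SD, n = 8 and 7). The neuronal splicing regulator gene Srrm4 (-0.46), the fibrillin gene Fbn2 (-0.79), Aff1 (-0.51), Zcchc14 (-0.31), Tbc1d24 (-0.31) and Arhgap23 (-0.21) also fell. Dbp, a clock-controlled transcription factor gene, rose from 48.3 ± 3.11 to 60.7 ± 5.79 CPM (0.33, adjusted p = 0.0282, 6 of 7 libraries above all IS control). Cep95 (0.54), the noncoding RNA Snhg11 (0.53), the cold-inducible gene Rbm3 (0.48), Tdp2 (0.36), Entr1 (0.35), Commd4 (0.31) and Pnp (0.28) rose as well. In all, 19 genes differed, 11 higher and 8 lower, and 1 of them by at least 2-fold.

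Of 29 lists, 8 were called with the preset correlation and 0 with an estimated one. The nuclear oxidative phosphorylation list (55 genes, median log2 fold change 0.13, adjusted p = 5.32e-09), the cytosolic ribosomal proteins (73 genes, 0.13, adjusted p = 1.23e-08) and the mitochondrially encoded genes (13 genes, 0.24, adjusted p = 1.61e-05) were higher as sets. They had 0 members called over all genes and 2, 0 and 5 higher when adjusted over the list alone, and gave adjusted p = 0.443, 0.588 and 0.443 with an estimated correlation. Of 20 immature neuron and proliferation genes 1 was lower (Dpysl3) and 3 were lower over the list alone (median -0.07, adjusted p = 0.00430, and adjusted p = 0.271 with an estimated correlation). The insulin, IGF and mTOR list (-0.09), glutamatergic synapse (-0.06), pyramidal cell (-0.11) and meninges (-0.20) lists were lower with 0 members called, and gave adjusted p = 0.443 to 0.599 with an estimated correlation. The 21 other lists gave adjusted p = 0.0680 to 0.915. Tfrc was at 127 ± 17.0 CPM against 117 ± 6.55 CPM (0.12, adjusted p = 0.440), and Insr, Igf1r, Bdnf, Camk2a, Mbp and Slc2a1 gave adjusted p = 0.193 to 0.986.

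The count of 19 was 206 with DESeq2 (94 higher and 112 lower), 9 with the 2 compared groups alone, 0 with the second title number as a block in edgeR (2515 genes had an unadjusted p under 0.05 without the block), 6 with the tissue list means as covariates and 58 without ID insulin replicates 3 and 5. It was 92 without ID insulin replicate 3 and 34 without IS insulin replicate 6. It was 0 to 12 without any 1 of IS insulin replicates 1 to 5, IS control replicates 1, 2, 4, 5, 7 and 8, ID control replicates 3 and 6 and ID insulin replicate 6. Of the 15 genes named here, 0 were called in every setting, and each lost its call in 3 (Dpysl3) to 25 (Commd4) of the 32 fits with 1 library left out, Srrm4 in 21.

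Whether the insulin response differed by diet was tested as the interaction of diet and insulin. It gave 145 genes, 79 with a more positive and 66 with a more negative insulin effect in ID than in IS pups. Within the same limits, Slc39a12 had the largest positive difference (log2 3.64, SE 0.60, adjusted p = 0.00433). Its means were 20.4 ± 10.5, 18.4 ± 16.1, 2.93 ± 0.675 and 32.5 ± 9.20 CPM in IS control, IS insulin, ID control and ID insulin. Single libraries ranged from 2.97 to 38.4 CPM in IS control and from 1.74 to 41.3 CPM in IS insulin. Mki67 (0.88, adjusted p = 0.00433), Clcn5 (1.18) and Nhs (0.94) also had more positive effects, and Prss12 (-1.53, adjusted p = 0.00519), Slc28a2 (-1.41), Akr1c15 (-1.11) and Ap1s3 (-1.07) more negative ones. Of 20 immature neuron and proliferation genes 4 had a more positive effect, Cenpf (0.84), Mki67, Dcx (0.44) and Dpysl3 (0.43), 0 a more negative one and 16 were not called. When adjusted over the list alone 8 were more positive. The list's median was 0.36, and it was the only 1 of 12 called lists that held with an estimated correlation (adjusted p = 3.03e-06, and adjusted p = 0.00545 with an estimated correlation).

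The precursor gene Gpr17 (0.47), and the myelin gene Mal (-0.74), the vascular genes Vtn (-0.61) and Itm2a (-0.41), Eif4ebp1 (-0.69), Ndufb10 (-0.31), Ndufa10 (-0.25), Mxi1 (-0.31) and Dbp (-0.49) were among the genes whose insulin effect differed. The oxidative phosphorylation (-0.13), ribosomal protein (-0.16), endothelium (-0.22), immediate early gene (-0.24), microglia (-0.17), glycolysis (median -0.12, mean 0.07) and meninges (-0.32) lists were called more negative. The oligodendrocyte precursor (0.15), GABAergic (0.16), thalamus (0.50) and blood (0.68) lists were called more positive. These 11 lists gave adjusted p = 0.182 to 0.528 with an estimated correlation. The other 17 lists gave adjusted p = 0.0782 to 0.984.

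The interaction count of 145 was 423 with DESeq2, 491 with limma voom, 94 without a count filter and 433 without ID insulin replicates 3 and 5. It was 9 with the second title number as a block, 6 of them shared with the 145, 26 with the tissue list means as covariates and 12 with the ID control libraries of number 69 alone. Leaving out 1 library gave 594 without ID insulin replicate 3, 391 without ID control replicate 1 and 232 without ID control replicate 2. It gave 40 without IS insulin replicate 2, 63 without IS control replicate 5, and 81 to 94 without any 1 of ID control replicates 5 and 7 and ID insulin replicates 5, 6 and 8. Slc39a12 and Mki67 were called in every setting, while of the 32 fits Slc28a2 lost its call in 18, Nhs in 8 and Clcn5 in 4.

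ID insulin was also compared with the 2 iron-sufficient groups. Against IS control, Tfrc was higher by 0.79 on the log2 scale (adjusted p = 1.35e-08). The lipoxygenase gene Alox15 was at 279 ± 125 against 65.0 ± 30.9 CPM (2.1, adjusted p = 2.98e-04) with all 8 ID insulin libraries above every IS control library. The blood list was higher too (median 0.98, with 4 of 9 genes called). IS control replicate 3 was highest of its group in Alox15, Alas2 and the blood list, and IS insulin replicate 4 in Alox15 and Slc4a1. Whether Alox15 follows blood content was not tested. Slc18a2 (1.72), Alas2 (1.46) and the cilium gene Cfap100 (1.4) were also higher, and Sncg (-1.66), the axonemal dynein gene Dnah8 (-1.54), Fosb (-1.23) and the retinol saturase gene Retsat (-1.19) lower. In all, 517 genes differed, 320 higher and 197 lower, and 19 of them were among the 45 called in ID control against IS control. Slc18a2 lost its call in 5 of 11 settings and without any 1 of 10 libraries, 6 of IS control and 4 of ID insulin, and Cfap100 in 3 settings and without IS control replicate 7 or ID insulin replicate 3. Against IS insulin, 378 genes differed, 204 higher and 174 lower. Alox15 (1.74), Slc4a1 (1.31), Grid2ip (1.3) and the cilium gene Cfap65 (1.14) were the most increased within the limits on symbol and level, and the carbonic anhydrase gene Ca3 (-2.49), Sncg (-1.61), Retsat (-1.32) and Dnah8 (-1.32) the most decreased. Of 32 fits with 1 library left out, Ca3 lost its call in 20, Grid2ip in 15 and Slc4a1 in 7, and of 11 settings in 7, 5 and 4.

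Against IS control 12 lists were called and 0 with an estimated correlation. Of 17 glucocorticoid-responsive genes 6 were lower and 11 not called, and 11 were lower when adjusted over the list alone. The median was -0.34 (adjusted p = 1.47e-08, and adjusted p = 0.0553 with an estimated correlation). Of 26 immediate early genes 5 were lower, and 6 over the list alone (median -0.23, adjusted p = 8.06e-08, and adjusted p = 0.106 with an estimated correlation). Against IS insulin 14 lists were called and 1 with an estimated correlation. Of 20 immature neuron and proliferation genes 4 were higher, including Cenpf (0.78), Mki67 (0.67) and Dcx (0.29), 0 lower and 16 not called, with 10 higher over the list alone (median 0.30, adjusted p = 0.00433 with an estimated correlation). The other lists called in these 2 comparisons gave adjusted p = 0.106 to 0.643 with an estimated correlation.

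Without ID insulin replicates 3 and 5 the counts were 182 against IS control and 391 against IS insulin. With DESeq2 they were 855 and 723, with the compared groups alone 247 and 146, and with the tissue list means as covariates 6 and 56. With the second title number as a block they were 380 and 177. Against IS control, leaving out IS control replicate 7 gave 240, IS control replicate 8 or ID insulin replicate 3 gave 285 each and ID insulin replicate 7 gave 902. Against IS insulin, leaving out any 1 of IS insulin replicates 2 to 5 gave 169 to 228, any 1 of ID insulin replicates 5, 6 and 8 gave 176 to 248, and ID insulin replicates 1 and 3 gave 605 and 751. Alas2 and Alox15 against IS control and Alox15 against IS insulin were called in every setting.

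Genes that iron deficiency altered and insulin moved back were counted as those called in ID control against IS control and with the opposite sign in ID insulin against ID control. Of the 45 genes, 12 were of this kind. Plac9, Aoc3, Mphosph6, Crot, Pltp, Sun2 and Cav2 were higher in ID control and lower with insulin, and Slc39a12, AC135826.1, Rab36, Gramd2b and Entpd5 were lower and then higher. These are all 12, whether or not the naming rule gave them. In Slc39a12 the log2 fold change was -2.81 and then 3.47, in Plac9 1.43 and then -1.13, and in the phospholipid transfer gene Pltp 0.41 and then -0.35. Low levels of Slc39a12 also occurred in iron-sufficient pups, at 2.97 CPM in IS control and at 1.74 and 3.45 CPM in IS insulin. What sets these levels was not tested. Tfrc was the 1 gene called in the same direction in both. Of the 12, 0 were called in ID insulin against IS control. That fold change is the sum of the 2 opposite ones by which these genes were selected. The lack of a call is thus largely set by the selection and is no separate evidence of a return.

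Both comparisons use the same ID control libraries, whose chance deviations push their fold changes in opposite directions. In 20 simulations with unchanged ID insulin libraries, 791.8 genes were called for ID control against IS control and 0.2 for insulin on average, against 45 and 589 in the data, so they do not measure how many of the 12 the shared libraries bring. Independent lists of these sizes would share 0.854 genes in opposite and 0.863 in the same direction. ID control was divided at random into 4 and 5 libraries 20 times, so that the comparisons shared no library. Each division gave a pair of counts, 40 in all, which are not independent. Their median was 2 (range 0 to 3) for opposite calls and 0 (at most 3) for calls in the same direction. With fewer ID control libraries in each comparison fewer genes are called, so the fall from 12 does not measure what the shared libraries bring. With number 69 compared with IS control and ID insulin with number 70 there were 4 opposite and 3 equal directions, and with the numbers exchanged 3 and 1. Across genes the covariance of the 2 fold changes was -0.0286, against -0.0157 on average (range -0.0184 to -0.0131) in these simulations, where the shared libraries alone link them. The covariance of mean log2 CPM differences was -0.0203 with ID control shared and -0.00700 on average (range -0.0182 to 0.0106) over 100 random divisions of it. With number 69 against IS control and ID insulin against number 70 it was -0.00119, and with the numbers exchanged -0.00722.

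The count of 12 was 34 with DESeq2, 67 with limma voom, 7 with the compared groups alone, 20 with the second title number as a block and 2 with the tissue list means as covariates. It was 25 without ID control replicate 1 and 6 or 7 without any 1 of ID control replicates 7 and 9 and IS control replicates 1, 2 and 8. It was 15 without ID insulin replicates 3 and 5.

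Inside ID control, libraries of number 70 were compared with those of number 69, the only place where this number varied within a group. Of 15008 genes tested, 33 differed, 11 higher and 22 lower in number 70. Ephx2, the soluble epoxide hydrolase gene, was at 1.25 ± 0.333 CPM in number 70 and 11.3 ± 0.949 CPM in number 69 (log2 fold change -3.16, SE 0.16, adjusted p = 2.41e-06; SD, n = 4 and 5). The ranges did not overlap. The mitochondrially encoded gene Mt-nd2 was at 8845 ± 305 against 5183 ± 365 CPM (0.77, adjusted p = 3.78e-04), with reads that nuclear copies may share. The radial glia gene Fabp7 (0.54) was higher and the myelin genes Mog (-0.47) and Cnp (-0.37) and Slc4a1 (-1.11) lower. These genes are not covered by the naming rule and were chosen after their values were seen. The count was 165 with DESeq2, 53 with limma voom, 16 with the second title number as a block and 11 with the Y-linked list mean as a covariate, and 4 to 24 when any 1 of the 9 libraries was left out.

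**Figure D3:**
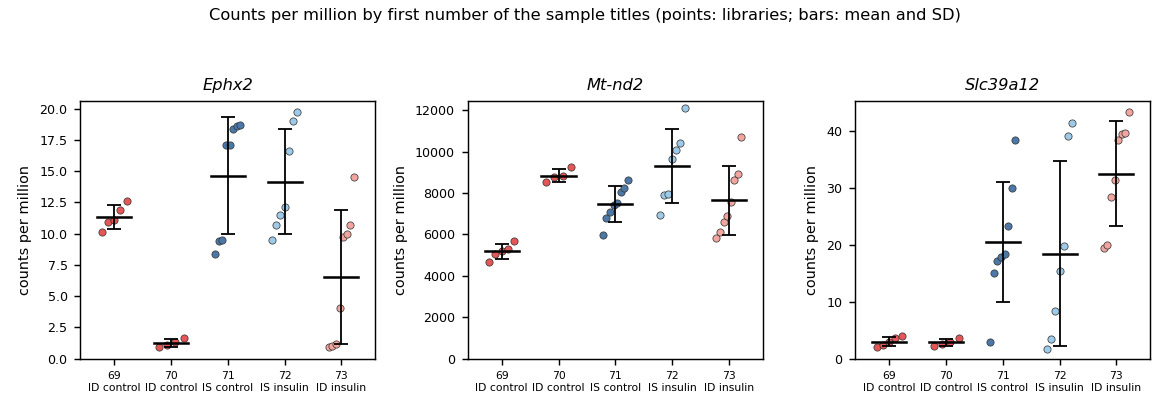
CPM (y axis, linear, starting at 0) of 3 genes by the first number of the sample titles (x axis), with each library as a point and mean and SD as bars. Ephx2 is at 1.25 ± 0.333 CPM in number 70 and 11.3 ± 0.949 CPM in number 69, both of them ID control, while Slc39a12 is low in both (2.87 ± 0.619 and 2.98 ± 0.786 CPM).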

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

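Of the tests in this part, the one on the first title number was chosen after the result was seen, as were the removal of ID insulin replicates 3 and 5 and the tissue list covariates that the others use.

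A library far from the others of its group was looked for in 357 groups of values, of which 35 had one by Dixon's test. With normally distributed values chance gives about 1 in 20 groups, or 17.9 of 357. Single genes were tested as CPM on a linear scale, where high values can lie far apart. The groups also share libraries and related genes. How many of the 35 are no more than chance would bring is therefore not known. Total counts were 28062630 in IS insulin replicate 6 and at most 23920278 in the others of its group.

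In 9 groups a list mean stood apart, on a log2 scale centred over all libraries. In IS control the blood list was at 0.99 in replicate 3, the endothelium list at -0.40 in replicate 5 and the glycolysis list at 0.31 in replicate 8. In IS insulin the glucocorticoid-responsive list was at 0.33 in replicate 4 and the glycolysis list at -0.16 in replicate 1. In ID insulin the choroid plexus list was at -1.48 and the meninges list at -0.73 in replicate 7, the glutamatergic synapse list at -0.40 in replicate 3 and the thalamus list at 1.73 in replicate 5.

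Single genes stood apart in 25 groups. ID control replicate 1 had the highest Isl1 (1.07 CPM), Patj (19.0 CPM), Prkcd (35.6 CPM) and Slc18a2 (2.88 CPM) and the lowest Ndufb10 (64.4 CPM). ID control replicate 2 had the highest Alas2 (38.2 CPM), Hbb (892 CPM) and Slc4a1 (26.2 CPM), and replicate 3 the highest Nfkbia (34.5 CPM). In IS control, replicate 3 had the highest Alas2 (32.1 CPM) and Alox15 (134 CPM), replicate 5 the highest Srrm4 (15.1 CPM) and replicate 7 the highest Snhg11 (55.1 CPM). In IS insulin, replicate 4 had the highest Alox15 (210.0 CPM) and Slc4a1 (31.7 CPM), replicate 1 the highest Tfrc (165 CPM) and replicate 7 the highest Fbn2 (4.73 CPM). In ID insulin, replicate 8 had the highest Baiap3 (129.7 CPM), Isl1 (5.23 CPM) and Slc18a2 (18.3 CPM), replicate 3 the highest Cfap65 (18.8 CPM) and Mbp (13590 CPM), replicate 5 the highest Grid2ip (11.6 CPM) and Prkcd (172 CPM), and replicate 7 the highest Dnah8 (4.56 CPM).

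The insulin effect differed between the diets, by the test of the interaction, in 145 genes. Among named genes the difference (ID minus IS, log2) was positive for Slc39a12 (3.64), Clcn5 (1.18), Nhs (0.94), Mki67 (0.88), Cenpf (0.84), Srrm4 (0.58), Gpr17 (0.47), Dcx (0.44), Dpysl3 (0.43) and Tbc1d24 (0.39). It was negative for Prss12 (-1.53), Slc28a2 (-1.41), Akr1c15 (-1.11), Ap1s3 (-1.07), Mal (-0.74), Eif4ebp1 (-0.69), Vtn (-0.61), Dbp (-0.49), Tdp2 (-0.47), Itm2a (-0.41), Pnp (-0.33), Ndufb10 (-0.31), Mxi1 (-0.31) and Ndufa10 (-0.25). The median difference of the immature neuron and proliferation list was 0.36.

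More genes were called for insulin in iron-deficient pups (589) than in iron-sufficient pups (19). By the same test, genes with an unadjusted p under 0.05 were closer in number, 3017 and 2515 of 15439. The gap thus depends on where the adjusted threshold falls, and 19 does not mean that insulin hardly acted in iron-sufficient pups. The size of the difference depends on the method and on single libraries: with DESeq2, fixed in advance, the counts were 819 and 206, and without ID insulin replicate 3 they were 529 and 92. Without ID insulin replicates 3 and 5 the counts were 358 and 58, a ratio of 6.17, and with the tissue list means as covariates 31 and 6, a ratio of 5.17, both past the limit of 5 set in advance for ruling these explanations out. Counts of genes are not independent, so after these ratios were seen they were set against their spread when each library is left out as well, with a count of 0 in the divisor taken as 1. The first ran from 1.09 to 381 over 30 fits, with more genes in iron-deficient pups in all 30. The second ran from 0.05 to 22 over 32 fits, with more genes in iron-deficient pups in 27. The difference thus kept its direction in most fits, but its size came near 1 or below in some, so neither explanation can be ruled out. With the covariates, the standard errors of the 589 genes grew by a median factor of 1.42 while their log2 fold changes kept a median ratio of 0.93 (quartiles 0.69 and 1.15), 7 changed sign and 25 were called, so much of the fall in the count may come from precision. Title numbers 69 and 70, both ID control, differed in 33 genes. Between number 69 and 4 ID insulin libraries a median of 10 genes differed (range 6 to 22) over 20 draws. A litter or another unit behind the number is thus a candidate source of part or all of the 589. The test does not limit its share, although the 33 fell to as few as 4 without 1 library. An effect of insulin that depends on diet stays open beside it.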

How the results depend on the processing

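The edgeR quasi-likelihood method of earlier versions, the removal of ID insulin replicates 3 and 5 and the tissue list covariates were chosen after the results were seen. The direction of every called gene the naming rule gave was the same in the alternatives run, except for Ptgds (0.17) and Tnnt2 (0.22) in ID insulin against ID control with the tissue covariates, where the cause was not tested.

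With DESeq2 the counts were 114 (ID control against IS control), 819 (ID insulin against ID control), 206 (IS insulin against IS control, 94 higher and 112 lower), 855 (ID insulin against IS control), 723 (ID insulin against IS insulin), 423 (interaction), 165 (title number 70 against 69) and 34 (moved back). With limma voom they were 242 (ID control against IS control), 491 (interaction), 53 (title numbers) and 67 (moved back). The cause was not tested. Without a count filter the interaction gave 94, with more genes tested.

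In fits of the compared groups alone, which have fewer libraries, the counts were 278 (ID insulin against ID control), 9 (IS insulin against IS control), 247 and 146 (ID insulin against IS control and IS insulin) and 7 (moved back). The interaction uses all groups and has no such value. With ID control of number 69 alone the counts were 150 (ID insulin against ID control) and 12 (interaction), and with number 70 alone 232 (ID insulin against ID control), from fewer libraries. With the Y-linked list mean as a covariate the title numbers gave 11.

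Without ID insulin replicates 3 and 5 the counts were 358 (ID insulin against ID control), 58 (IS insulin against IS control), 182 (ID insulin against IS control) and 433 (interaction). With the tissue list means as covariates they were 10, 31, 6, 6, 56 and 26 in the order of ID control against IS control, ID insulin against ID control, IS insulin against IS control, ID insulin against IS control, ID insulin against IS insulin and the interaction, and 2 for genes moved back.

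The second title number does not pair the libraries: 40 pairs with the same number had a mean correlation of 0.01 (-0.19 to 0.25), 343 others -0.00, and 2 of 32 libraries matched their own number best. As a replicate block it gave 0 (IS insulin against IS control, by edgeR, where 2515 genes had an unadjusted p under 0.05 without it), 177 (ID insulin against IS insulin), 9 (interaction), 16 (title numbers) and 20 (moved back). In IS control, IS insulin and ID insulin the second number followed the Y-linked transcripts. Libraries numbered 5 or less had at most 0.529 CPM of Eif2s3y and Kdm5d, and those numbered 6 or more had more than 10 CPM. In ID control, with numbers up to 5, it did not. The block can therefore also take up differences that go with these transcripts.

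Leaving out each library in turn gave 23 to 61 genes for ID control against IS control, 323 to 806 for ID insulin against ID control, 0 to 92 for IS insulin against IS control, 240 to 902 for ID insulin against IS control, 169 to 751 for ID insulin against IS insulin, 40 to 594 for the interaction, 4 to 24 for the title numbers and 6 to 25 for genes moved back.

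Of 29 lists, camera with an estimated correlation called 0, 2, 0, 0, 1 and 1 and fry 3, 7, 1, 6, 3 and 3 in the order above, against 11, 17, 8, 12, 14 and 12 with the preset correlation.

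Some fold changes that were not called changed sign. In ID control against IS control, Slc2a1 was at -0.000181 with limma voom and -0.0342 with number 70 alone (-0.0338 to 0.0595 leaving out libraries), and Camk2a at 0.0108 with number 70 alone. Insr was at 0.0524 with the replicate block and 0.0232 with number 69 alone (-0.0450 to 0.0171), and Igf1r ran from -0.113 to 0.0130. In ID insulin against ID control, Insr was at 0.00689 with limma voom, 0.0242 with number 70 alone and 0.0299 with the tissue covariates (-0.0383 to 0.0146). In IS insulin against IS control, Bdnf was at 0.0286 with limma voom and 0.000566 with the Y-linked covariate (-0.0454 to 0.0414). These values are all near 0.

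The count of called named genes that stayed called in every alternative and without each library was 3 of 16, 2 of 63, 0 of 15, 2 of 8, 1 of 8 and 2 of 8 in the same order. In simulated data with these totals, 70% of genes changed 1.25-fold were recovered for ID insulin against ID control and 52% for IS insulin against IS control. This limits what can be seen of smaller changes. The simulated genes varied independently, without shared differences such as tissue content, so recovery in the real libraries may be lower.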

Other observations

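The tests on insulin treatment and on the time of day were chosen after the result was seen, as were the core clock and motile cilia lists.

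Other divisions of the same libraries into groups of the same sizes show how often a division at random gives as large a count. Of 100 divisions, the real one included, 1 gave as many genes as ID control against IS control (45, and 4 at most in another), 1 as many as ID insulin against ID control (589 and 8), 2 as many as IS insulin against IS control (19 and 33), 1 as many as ID insulin against IS control (517 and 211), 1 as many as ID insulin against IS insulin (378 and 360), 1 as many as the interaction (145 and 59) and 4 as many as the title numbers (33 and 111). For 5 counts the real division thus ranked first of 100, by a small margin for ID insulin against IS insulin, so divisions at random rarely reach them. For the 19 and the 33 fewer than 5 of 100 divisions gave as many, but the largest gave more. Single pups were divided as if exchangeable, which would not hold if pups of a group shared a litter. The ranks do not separate the groups from the title numbers. Divisions that gave 111 or 360 genes point to structure among the libraries beyond the groups. For genes moved back (12, and 1 at most in another division) the divisions decide nothing, because the smaller of the 2 counts of calls was at most 1 in the 99 others and an overlap of 12 was out of reach.

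For counts of called lists, 1 of 100 divisions gave as many as ID insulin against ID control (17, and 15 at most in another). The real division thus ranked first there by a small margin. Chance cannot be excluded for the lists of ID control against IS control (11 and 14, with 12 divisions as large), IS insulin against IS control (8 and 15, with 46), ID insulin against IS control (12 and 18, with 19), ID insulin against IS insulin (14 and 17, with 7) and the interaction (12 and 16, with 14). The medians of the other divisions were 7 to 9 lists, so a preset correlation of 0.01 calls several lists in these libraries with no difference between groups.

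In 9 genes the iron-sufficient libraries fell into separate steps: Dr1, Asb15, Fcrl2, Mmp2, Chd1l, Rps9, RGD1562420, LOC100910575 and AABR07039356.2, which were chosen for this after their values were seen. Libraries of IS control lay on both steps in 100% of them, which rules out insulin treatment as the source. Inherited variants that differ between families may give such steps. They were predicted to put step genes among those called between groups, and 0% of the 9 were called in ID insulin against ID control, against 3.82% of other genes. Genes chosen for wide gaps within the IS groups have a large spread in the shared fit, which makes a call hard to reach. The 0% met the limit set in advance for ruling variants out. Because 9 genes allow a share of up to 33.6% (exact 95% limit), that limit was judged too lax after the value was seen. The test decides nothing, and the question stays open. Chd1l was on the upper step in 5 libraries of title number 69, 1 of number 70 and 0 of number 73, and Asb15 in 1, 2 and 8. Fcrl2 was on it in 0 libraries of any of these numbers. The other step genes had libraries on both steps in most numbers.

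Ephx2 was at 0.893 to 1.67 CPM in 7 libraries of the series, at 4.06 CPM in 1 and at 8.34 to 19.7 CPM in the 24 others. All 4 libraries of title number 70 were among the 7.

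Immediate early genes were lower in ID insulin than in ID control, with a median log2 fold change of -0.29. With the means of the pyramidal cell, dentate and glutamatergic synapse lists as covariates the median was -0.27 (p = 0.0111 with an estimated correlation), and with those of the meninges and endothelium lists -0.28 (p = 0.00231), both above the share of the original value that was asked for in advance. A lower share of hippocampal neurons and less meningeal and vascular tissue are therefore argued against as the whole source, although only 1 and 2 of the 5 called genes were called with the covariates, with which the median SE of the list's genes grew from 0.116 to 0.134 and 0.145. Time of day at collection cannot be told apart: 2 core clock genes other than Per1 were called, Nr1d1 and Per3, and the list's mixed p was 0.0477 (fry), short of the 3 genes that were asked for. An effect of insulin, handling before collection and the unit behind the title number stay open as untested.

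The list of 34 motile cilia and ependyma genes was composed after genes of this kind had been seen among those called, so its tests are not independent evidence. Its median log2 fold change was 0.67 in ID insulin against ID control with 12 genes higher (p = 0.0581 with an estimated correlation) and 0.86 against IS control with 21 higher (p = 0.0251). Without ID insulin replicates 3 and 5 the medians were 0.42 with 3 higher and 0.64 with 8 higher. The core clock list of 15 genes had medians of -0.10 to 0.05 over the 6 comparisons. A median does not register genes that move in opposite directions. The mixed p of the list (fry) was 0.0102 to 0.0477 in the comparisons with an insulin group. In ID control against IS control it was 0.453. Time of day at collection therefore cannot be set aside in the comparisons with an insulin group.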
